A study of Mus musculus with 22 samples.

How the data were processed

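Spleen RNA of 22 mice was measured on a 1-colour Illumina bead array with biotin label. The values used here are the log2 intensities that the authors deposited for each of the 22 arrays. The authors had normalized them: all 22 arrays hold the same distribution of values, as quantile normalization between arrays gives, and they are not centred per gene. The unit was read from the values: a base of 2 puts the highest intensity inside a 16-bit scanner range, which a natural or decimal logarithm would exceed. The method of background correction and the software are not given in the sources used here. The deposited table of unnormalized intensities was not used, because its 44 columns of per-sample values carry names that match no mouse. The plan had been to process that table with the neqc method, and its stated fallback, normalized values on the log2 scale, took its place. Their number, 22 arrays, limits the precision.

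The array holds 45281 probes, of which 34885 had 1 gene listed, 18 several and 10378 none. Probes were kept when they exceeded the 40th percentile of an array in at least 7 of the 22 arrays, which left 30013. A gene with several probes was represented by the probe with the highest mean over all arrays, and probes with no or several genes stayed as features of their own. This gave 20463 features, of which 14500 were named genes and 5963 were not. Gene names and the order of genes along the chromosomes follow the mouse assembly GRCm38.p6.

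Mice were grouped as the titles give them: Bim-deleted with disease, Bim-deleted without disease, and cyclin D1 transgene alone. The titles also give the stimulus of each mouse and a number, written here as A for sheep red blood cells alone, I for added irradiation and P for added pristane, followed by the number. The design text speaks of 7 mice with the transgene alone and the titles list 8, and all 8 were used. Each mouse was taken as a replicate, as the labels give it.

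The 3 group comparisons came from 1 limma model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes without trend). The stimuli were compared in an additive model of group and stimulus, and the interaction in a model with a mean for each of the 9 combinations. P-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05, and every limma p is two-sided. Gene lists, 26 in all with 347 entries, of which 289 were measured, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists. Camera compares a list with the other genes. Fry tests whether the list's own genes move one way on balance. A list score is the mean over members of the log2 intensity minus the gene's mean over the 22 mice. Scores of diseased and non-diseased Bim-deleted mice were compared by a two-sided exact permutation test over all 3432 splits. The groups, tests, lists, named-gene rule and most alternatives were chosen before the data were examined.

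Named genes followed a rule: the 10 largest rises and 10 largest falls among named genes past the threshold, or the 3 genes with the smallest p where none passed. Ccnd1 and Bcl2l11 were always named. The 4 members with the smallest p were added from each list past camera, and up to 4 members of any other list where their own adjusted p passed. Ctla4, Sox11, Xist and Eif2s3y in the results, and several genes of the closing part, were named outside this rule.

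The pipeline was tested on simulated data with 20463 features and the same group sizes. For diseased against non-diseased Bim-deleted mice it recovered 85.1% of features given a log2 change of 0.5, 97.0% at a change of 1 and 100.0% at a change of 2, with 8 false calls among 196. With no simulated change it made 0 calls with limma. The share recovered at a log2 change of 0.5 was 89.6% for non-diseased Bim-deleted against transgene-only mice and 83.6% for diseased against transgene-only mice. The simulated features were independent and normal, and the changes were placed on features at random. Real genes move together, with an estimated correlation of 0.84 in the neutrophil list, and many features lie near background, where values spread little. The shares recovered and the false calls therefore need not hold for genes above background.

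Alternatives covered the probe filter, every probe as a feature, eBayes with trend and robust settings, array weights, fitting only the groups compared, stimulus as a covariate, the title number as a block, and leaving out each mouse in turn. Added after seeing the data were a 60th percentile filter, leaving out the 5 pristane mice, and the erythroid list score or the Xist level of each mouse as a covariate. The result of the erythroid list with its own score as a covariate is not given. The list counts and the adjustment over lists in that setting do include it.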

Results

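Gene expression was measured in whole spleens of 22 mice that carry a cyclin D1 transgene, 1 array per mouse. In 14 of them Bim, the pro-death BCL2 family protein encoded by Bcl2l11, was also deleted in B cells. By histopathology 7 of these had disease and 7 did not. A further 8 mice carried the transgene alone and had no disease. All mice received sheep red blood cells (SRBC), a T cell dependent antigen: 8 received SRBC alone, 9 also irradiation and 5 also pristane, an oil that provokes inflammation. The diseased group held 3, 3 and 1 mice of these stimuli, the non-diseased Bim-deleted group 2, 3 and 2, and the transgene-only group 3, 3 and 2. On every array the median log2 intensity was 6.55 and the highest 14.40. Across features, arrays of the same group correlated at r = 0.906 to 0.9905; features are not independent replicates. The closest pair of arrays differed by an SD of 0.188 per feature, so no array was a duplicate of another.

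The altered genes themselves were examined first. Ccnd1, which encodes cyclin D1, had a log2 intensity of 9.92 ± 0.40 (SD, n = 7) in diseased Bim-deleted mice, 10.09 ± 0.47 (n = 7) in non-diseased ones and 10.32 ± 0.47 (n = 8) in transgene-only mice. The difference between the Bim-deleted groups was -0.17 ± 0.23 (SE; limma adjusted p = 0.804). Bcl2l11 was 8.35 ± 0.49 in diseased, 7.79 ± 0.12 in non-diseased Bim-deleted and 8.23 ± 0.23 in transgene-only mice. Diseased minus non-diseased was 0.56 ± 0.16 (limma adjusted p = 0.0796, exact permutation p = 0.0175, unadjusted). Non-diseased Bim-deleted minus transgene-only was -0.44 ± 0.16 (limma adjusted p = 0.9999 over all 20463 features, no permutation test run). These 2 groups overlapped little, at 7.62 to 7.95 and 7.88 to 8.52, and diseased mice spanned 7.64 to 8.88. The adjusted p therefore does not show that Bcl2l11 was unchanged by the deletion. Another Bcl2l11 probe stood at 7.41 ± 0.37, 6.998 ± 0.11 and 7.23 ± 0.15 in the same order of groups, and 2 more probes were at background in every group, at 6.48 to 6.59 (diseased against non-diseased exact permutation p = 0.674 and 0.762, unadjusted). The 2 other Ccnd1 probes had an exact permutation p of 0.469 and 0.390. Without diseased mouse P_1 the Bcl2l11 difference was 0.64 (limma adjusted p = 0.0372) and without diseased mouse A_3 it was 0.68 (0.0232). Whether the probes lie in the deleted part of Bcl2l11, or detect the Ccnd1 transgene, is not given in the files.

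The comparison of diseased with non-diseased Bim-deleted mice asks what accompanies disease at the same Bim and transgene genotype. The share of the sexes probably differed between these groups, as described below for Xist and Eif2s3y. Zbtb32, a transcriptional repressor of lymphocytes, rose 5.28-fold, from 7.90 ± 0.58 to 10.30 ± 0.91 (SD, n = 7 each; log2 change 2.40 ± 0.33 SE, limma adjusted p = 9.20e-04). Ackr2, a receptor that scavenges inflammatory chemokines, rose from 7.42 ± 0.21 to 9.22 ± 0.65 (adjusted p = 4.54e-04). Twsg1, a secreted protein that binds bone morphogenetic proteins, rose from 9.26 ± 0.19 to 10.41 ± 0.19 (adjusted p = 4.10e-06). Ackr2 and Twsg1 were each higher in 7 of 7 diseased mice than in every non-diseased Bim-deleted mouse, and Zbtb32 in 6 of 7; complete separation of 7 from 7 mice has a chance of 5.83e-04 for a gene fixed in advance, which does not apply to genes picked among 20463 for their change. Acoxl, a gene next to Bcl2l11, rose by 1.81 ± 0.34 (adjusted p = 0.00963) from 6.79 ± 0.47, near background, and diseased mouse A_3 stood at 6.499.

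Some genes that rose were at background in non-diseased mice, near the array median of 6.55, so that the size of their rise is limited by the background and is not ranked. Tnfrsf19, a TNF receptor family member, stood at 6.52 ± 0.03 in non-diseased and 7.82 ± 0.71 in diseased Bim-deleted mice (adjusted p = 0.00277). AF067061 (6.53 in non-diseased mice, difference 2.10 ± 0.34) and Tcstv1 (6.56, 1.71 ± 0.32) belong to a family of near-identical genes and may share probe signal, and 1810046K07Rik stood at 6.59 (1.63 ± 0.25). Diseased mouse I_2 was also at background for these 4 genes. Above background, C130026I21Rik rose by 1.87 ± 0.35 and Rap1gap, which switches off the GTPase Rap1, by 1.16 ± 0.20. The falls were smaller. Per1, a core clock gene, fell by 0.79 ± 0.16 (adjusted p = 0.0193), Rab27a, which acts in granule secretion, by 0.67 ± 0.14 (0.0211) and Arrb2, a beta-arrestin, by 0.67 ± 0.16 (0.0341). Cdk5r1, an activator of Cdk5, fell by 0.57 ± 0.11 and Gadd45g, a stress-induced gene, by 0.56 ± 0.11. Ntn5, Trps1, Abcb1b, Map11 and Itprip fell by 0.55 to 0.61. Mdm2, the ubiquitin ligase that restrains p53, fell by 0.41 ± 0.09 (adjusted p = 0.0241), and Marco, a scavenger receptor of marginal zone macrophages, rose by 0.78 ± 0.18 (0.0297). Of 25 alternatives the call was lost in 14 for Ntn5, 10 each for Abcb1b, Arrb2, Map11 and Marco, 8 each for Itprip and Trps1 and 7 for Mdm2. An unadjusted p under 0.05 was found for 3013 features, against 1023 expected with no difference. In all, 238 features rose and 136 fell, 374 of 20463, and 21 rises and 0 falls by limma exceeded 2-fold. The count was 91 when only these groups were fitted, 745 with array weights and 806 without the pristane mice, and lay between 141 (without diseased mouse A_1) and 692 (without P_1) on leaving out single mice. It was also under 374 by over 1.5 times without diseased I_1 (163) or A_2 (164), or non-diseased P_2 (167), A_1 (178), I_1 or I_3 (222 each).

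**Figure D1:**
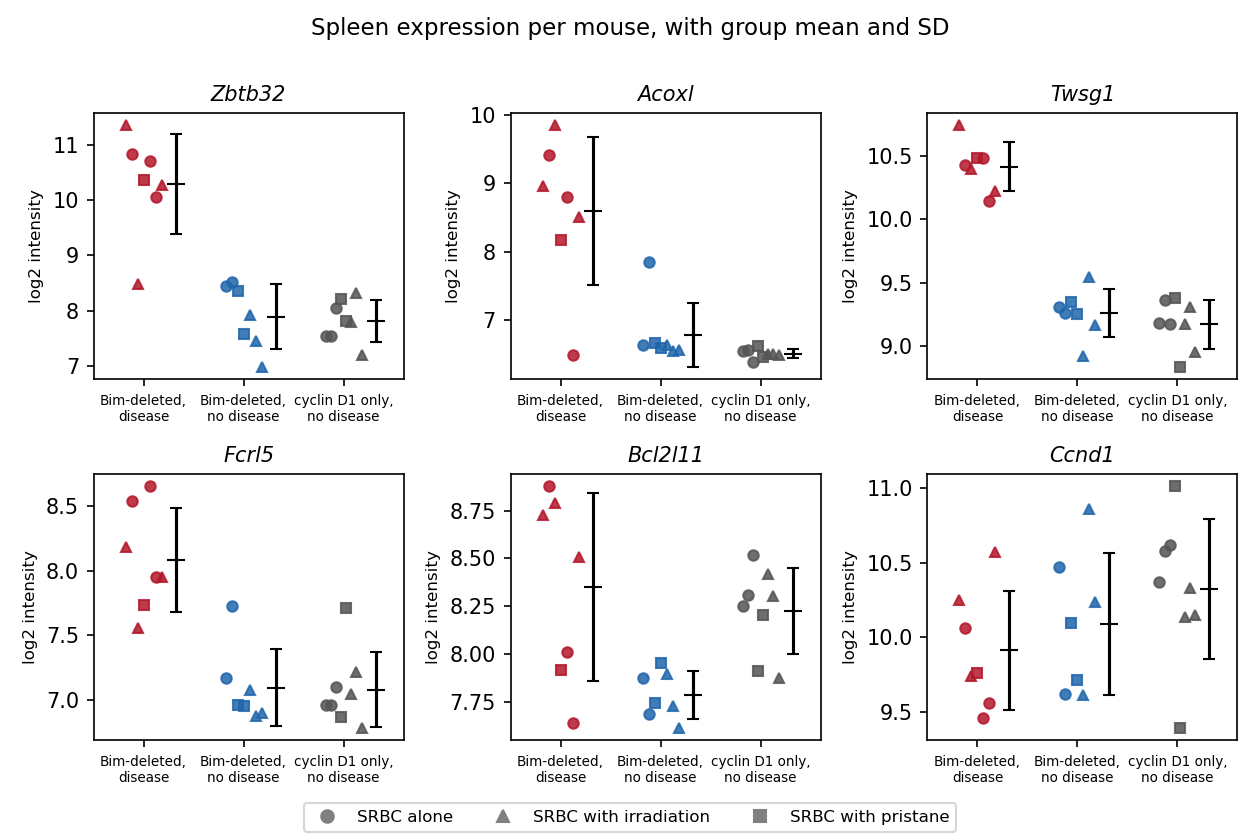
Log2 intensity (y axis) of 6 genes in each mouse by group (x axis); each point is a mouse, shaped by stimulus, and the bar is the group mean with SD. Twsg1 separates all 7 diseased mice (mean 10.41) from the 7 non-diseased Bim-deleted mice (9.26), while the groups overlap for Ccnd1 (9.92 and 10.09).

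Among the 26 gene lists, B-1a cell markers had the smallest camera p. B-1a cells are a self-renewing B cell subset that carries CD5. Of the 6 measured members 4 rose, and 5 did when adjusted over the list alone: Zbtb32, Fcrl5, a B cell Fc receptor-like protein (from 7.09 ± 0.30 to 8.08 ± 0.40, adjusted p = 0.00577), the tetraspanin Cd9 (from 9.24 ± 0.37 to 10.12 ± 0.26, 0.0209) and Bhlhe41, a transcription factor of B-1a cells (by 0.12 ± 0.02, near background at 6.56, 0.00726). Ctla4, named outside the rule for named genes, was 0.72 ± 0.20 higher and passed over the list alone. The median change was 0.80 (camera adjusted p = 6.46e-10; adjusted p = 0.00445 with an estimated correlation; fry 8.05e-06). The B-1a score was 0.60 ± 0.24 in diseased, -0.28 ± 0.19 in non-diseased Bim-deleted and -0.28 ± 0.17 in transgene-only mice. Diseased minus non-diseased was 0.78 within SRBC alone and 0.92 within irradiation. All 7 diseased mice scored above all 7 non-diseased ones (exact permutation p = 5.83e-04, the smallest that the splits can give; 0.0152 adjusted over 26 lists). Cd5 itself did not pass the filter.

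Other lists passed camera only at the preset correlation. DNA replication and G1/S genes were higher in all 22 measured members, with 0 past limma over all genes or adjusted over the list alone, a median of 0.27 and a camera adjusted p of 0.00414 (adjusted p = 0.871 with an estimated correlation); Gins2 was 0.36 higher and Tyms 0.47. The mean difference of 0.23 was 0.92 within SRBC alone and 0.05 within irradiation, and it was 0.013 with the Xist level as a covariate (camera adjusted p = 0.801) and 0.088 with the erythroid score (0.249). Of 11 D-type cyclins, CDKs and inhibitors 0 rose over all genes and 2 adjusted over the list alone, with a median of 0.13 and a camera adjusted p of 0.0411 (adjusted p = 0.753 with an estimated correlation); Ccnd2 was 0.67 ± 0.18 higher (limma adjusted p = 0.0560). Pan-B cell markers had a median of 0.15 over 14 members, 0 past limma, and a camera adjusted p of 0.0411 (adjusted p = 0.871 with an estimated correlation). Their mean difference of 0.25 was -0.014 without the pristane mice (camera adjusted p = 0.985), and the call was lost in 13 of 25 alternatives. T cell markers were lower in 11 of 12 members, 0 past limma, with a median of -0.29 and a camera adjusted p of 0.0416 (adjusted p = 0.871 with an estimated correlation); Bcl11b was -0.69 and Cd3d -0.79. The call was lost in 11 of 25 alternatives for T cells and 9 of 25 for D-type cyclins: with the Xist level the T cell mean went from -0.35 to -0.13 (camera adjusted p = 0.656) and the D-type cyclin mean from 0.17 to 0.084 (0.477), and with the erythroid score they were -0.19 (0.249) and 0.15 (0.102). Beside these, erythroid markers had a median of 0.47 (camera adjusted p = 0.119) and neutrophil and granule markers of -0.73 (0.119).

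The remaining lists did not pass camera, although in some alternatives the mitosis list (10 of 25, adjusted p down to 4.47e-06 without the pristane mice), the macrophage list (7 of 25), the erythroid list (5 of 24) and the neutrophil list (5 of 25) did. So did the plasma cell list (4 of 25), the follicular list (3 of 25), and the germinal centre, BCL2 family, interferon and megakaryocyte lists (1 of 25 each). Median changes were 0.11 for mitosis, 0.07 for macrophages, 0.06 for MYC targets, 0.03 for marginal zone B cells, 0.02 for the BCL2 family and p53 targets each, 0.011 for pancreas and 0.0096 for immediate early and heat shock genes. They were -0.0021 for stroma, -0.0090 for interferon response, -0.014 for dendritic cells, -0.016 for genes named in mantle cell lymphoma, -0.05 for NF-kB targets, -0.06 for adipose, -0.11 for plasma cells, -0.17 for germinal centre B cells, -0.21 for megakaryocytes, -0.21 for follicular B cells and -0.27 for NK and cytotoxic cells. Mean and median differed in sign for p53 targets, marginal zone, interferon response, immediate early and adipose genes. The germinal centre score of diseased minus non-diseased mice was -0.27 (exact permutation p = 0.00874, adjusted 0.114). Sox11, on the mantle cell lymphoma list and also named outside the rule, was near background in every group at 6.55 ± 0.06 in diseased mice. Xist and Eif2s3y, sex-linked genes chosen after their values were seen, stood at 7.93 ± 0.80 and 6.74 ± 0.75 in diseased and 6.95 ± 0.85 and 7.68 ± 0.81 in non-diseased Bim-deleted mice (exact permutation p = 0.0548 and 0.0682). Each gene ranged from background upwards in both groups. Xist spanned 6.39 to 8.73 in diseased and 6.43 to 8.51 in non-diseased mice, and Eif2s3y 6.40 to 8.43 and 6.47 to 8.36. The Eif2s3y mean of diseased mice (6.74) lay near its lowest value, so most of them were near background. In non-diseased mice the mean (7.68) lay nearer its highest value, so most were above background. Higher Xist and lower Eif2s3y go with female mice, so the diseased group probably held a larger share of females. The labels give no sex, so the exact share is not known. Sex and disease are therefore not cleanly separated in this comparison.

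**Figure D2:**
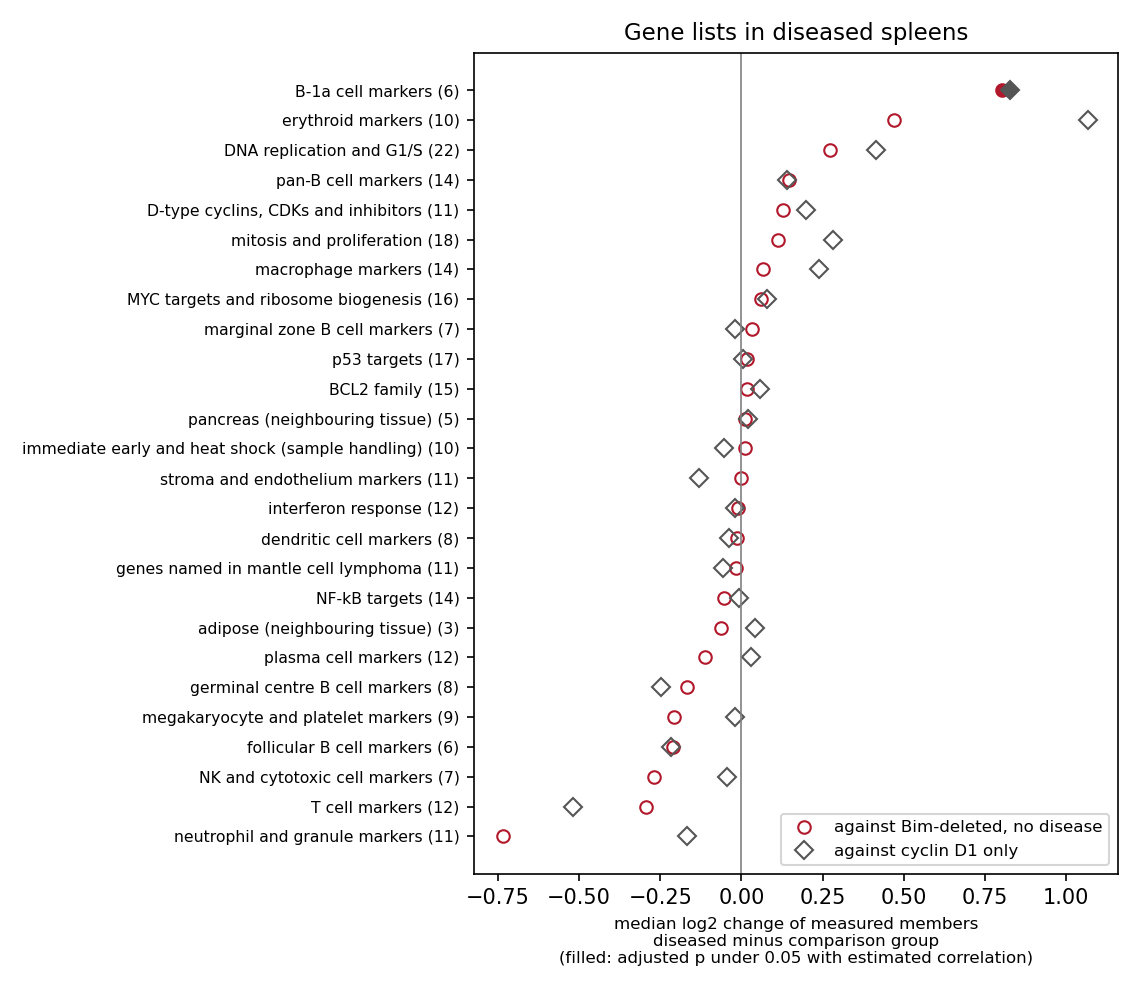
Median log2 change (x axis) of the measured members of each gene list (y axis, number of members in parentheses) in diseased mice against each comparison group; filled symbols have an adjusted p under 0.05 with an estimated correlation. The B-1a list alone is filled, at 0.80 against non-diseased Bim-deleted mice and 0.83 against transgene-only mice.

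Non-diseased Bim-deleted mice were compared with transgene-only mice, which sets Bim deletion against intact Bim without disease. The groups may differ in more than Bim. Psmb9 was low in 5 of 7 and 0 of 8 of these mice, and Hbb-b2 in 0 of 7 and 5 of 8. Both were picked after their values were seen, and the cause was not tested. By limma 0 of 20463 features passed, and 679 had an unadjusted p under 0.05, fewer than the 1023 expected with no difference. The smallest p-values belonged to Cemip2, a hyaluronidase (-0.48 ± 0.10), Cap1, an actin regulator (-0.56 ± 0.13), and Tceanc2 (0.23 ± 0.05), none significant at an adjusted p of 0.9999. Plasma cell markers were higher in all 12 measured members, with 0 past limma over all genes, a median of 0.23 and a camera adjusted p of 3.17e-04 (adjusted p = 0.934 with an estimated correlation); Tnfrsf17, the receptor BCMA, was 0.46 higher and Mzb1 0.47. DNA replication genes (median 0.16, camera adjusted p = 0.0118), erythroid markers (0.56, 0.0118), T cell markers (-0.18, 0.0342) and neutrophil markers (0.53, 0.0471) also passed camera at the preset correlation, each with an adjusted p = 0.934 with an estimated correlation. Of 26 alternatives the T cell call was lost in 14, the neutrophil call in 12 with 2 more reversed, the DNA replication call in 7 with 1 more reversed and the plasma cell call in 2, and the erythroid call was lost in 7 of 25. The list count fell from 5 to 0 without the pristane mice, and to 0 by fry. Without those mice the T cell mean stayed at -0.186 against -0.189 (camera adjusted p = 0.168), so its lost call does not show that they carry the difference. The means of the other lists went from 0.61 to 0.18 (erythroid), 0.46 to -0.26 (neutrophil), 0.24 to 0.12 (plasma cell) and 0.15 to 0.053 (DNA replication).

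Diseased Bim-deleted mice were also compared with transgene-only mice. Zbtb32 rose 5.61-fold (2.49 ± 0.32, adjusted p = 2.46e-04) and was higher in 7 of 7 diseased mice than in every transgene-only mouse. Hbb-b2, a beta globin whose probe may share signal with its near-identical copy, rose by 2.61 ± 0.65 (0.0228), a size limited by transgene-only mice A_2, A_3 and P_1, near background at 6.66 to 6.68. C130026I21Rik rose by 2.25, Ackr2 by 1.57 and Diras2, a Ras-like GTPase, by 1.48 ± 0.40 (0.0335). Acoxl (difference 2.09, adjusted p = 0.00145), AF067061 (2.07), Tcstv1 (1.71), 1810046K07Rik (1.69) and BC018473 (2.57 ± 0.74, 0.0469) also rose, but from the background, at 6.46 to 6.56 in transgene-only mice, so that the size of these rises is limited by it and is not ranked. Hbb-b2 and BC018473 overlapped between diseased and non-diseased Bim-deleted mice. Hbb-b2 stood at 10.77 to 11.60 in diseased and 9.69 to 11.42 in non-diseased Bim-deleted mice. BC018473 was near background in 2 of 7 mice of each of these groups and in all 8 transgene-only mice. Among falls, Satb1, a chromatin organizer of T cells, fell by 1.57 ± 0.40 (0.0271), Stat4, which carries interleukin-12 signals, by 1.17 ± 0.27 (0.0161), and Bcl6, the master regulator of germinal centres, by 1.002 ± 0.24 (0.0181, lower in 7 of 7 diseased mice). Thumpd1, Prg2, Pxdc1, Myl4, C4b, Bcl11b and Gpr171 fell by 1.01 to 1.34. Cr2, Notch1, Mdm2, Junb and Prf1 fell by 0.36 to 0.59, and Cdkn2b rose by 0.35. Of 26 alternatives the call was lost in 18 for BC018473, 17 for Prg2, 16 for Notch1, 14 each for Bcl11b and Diras2, 12 each for C4b, Prf1 and Cdkn2b, 11 for Thumpd1, 9 for Myl4 and 8 for Satb1. Ccnd1 was -0.41 (adjusted p = 0.327) and Bcl2l11 0.13 (0.723).

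B-1a markers had the smallest camera adjusted p with an estimated correlation in this comparison: 5 of 6 rose, 5 adjusted over the list alone, with a median of 0.83 and a camera adjusted p of 1.97e-07 (adjusted p = 0.0185 with an estimated correlation; fry 1.49e-05). T cell markers were lower in 12 of 12 members, of which 1 fell and 5 fell adjusted over the list alone, with a median of -0.52 and a camera adjusted p of 6.31e-04 (adjusted p = 0.769 with an estimated correlation). DNA replication genes had a median of 0.42 (camera adjusted p = 4.24e-06), mitosis genes of 0.28 (0.00258) and erythroid markers of 1.07 (0.0013), with 0 members past limma and an adjusted p = 0.769 with an estimated correlation in each. With the erythroid score as a covariate the DNA replication mean went from 0.38 to 0.054 (camera adjusted p = 0.499), the T cell mean from -0.54 to -0.17 (0.266) and the mitosis mean from 0.28 to -0.025; the mitosis mean was 0.15 with the Xist level (0.123). An unadjusted p under 0.05 was found for 4127 features, against 1023 expected with no difference. In all 1069 features passed, 459 rising and 610 falling, of which 31 and 11 exceeded 2-fold. The count lay between 576 (without diseased mouse A_2) and 1960 (without transgene-only mouse P_2) on leaving out single mice, with 615 without diseased A_1, 696 without I_1, 684 without transgene-only I_3 and 707 without A_2. It was 2618 with array weights and 2690 without the pristane mice.

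The lists of changed features overlapped. Of those that rose in diseased mice, 209 did so against both other groups, and 115 fell against both, with 0 in opposite directions by limma. Independence would give 5.34 and 4.05. The comparisons share the 7 diseased mice, which alone raises an overlap. In 20 simulations of independent features without any effect, in which the mice were shared too, at most 1 feature overlapped. Without any effect almost no feature is called, so these simulations cannot show how much the shared mice add. With those mice split between the comparisons, the overlap had a median of 53 rises (10 to 67) and 2 falls (0 to 18) over 35 splits. Each split left fewer diseased mice in each comparison, which by itself can lower the number of calls. The drop from 209 and 115 therefore does not measure what the shared mice add.

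Irradiation with SRBC was compared with SRBC alone. By limma 0 features passed, and 958 had an unadjusted p under 0.05, fewer than the 1023 expected with no difference. Dnajc16 (0.33 ± 0.07), Heatr5b (0.11) and Grpel2 (0.08) had the smallest p-values and were not significant (adjusted p = 0.789 each). T cell markers had a median of -0.33 (camera adjusted p = 0.00177; adjusted p = 0.803 with an estimated correlation). P53 targets had a median of 0.07 (camera adjusted p = 0.00905; adjusted p = 0.580 with an estimated correlation), with Sesn1, a stress-induced p53 target, 0.53 ± 0.18 higher, and 0 members past limma. Erythroid markers had a median of 0.55 (camera adjusted p = 0.0254; adjusted p = 0.803 with an estimated correlation). In mice without disease alone the p53 mean went from 0.097 to 0.049 and lost its call (camera adjusted p = 0.499), and with the erythroid score the T cell call was lost (-0.21, 0.0517). The erythroid call was lost in 9 of 24 alternatives, each of which left out 1 mouse: non-diseased Bim-deleted A_1, A_2, I_1 or I_3 or transgene-only A_2, A_3, I_1, I_2 or I_3 (adjusted p = 0.0541 to 0.165). The list count was 8 with the erythroid score as a covariate and 7 in mice without disease alone, and 0 by fry.

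Pristane with SRBC was compared with SRBC alone. Oas1g and Oas2, interferon-induced sensors of viral RNA, rose by 1.63 ± 0.26 (adjusted p = 0.0380) and 1.28 ± 0.19 (0.0373), and Clec4a4, a lectin receptor of dendritic cells, fell by 0.23 ± 0.04 (0.0380), to 6.51 and so to background, which limits the size of the fall. Of 21 alternatives the call was lost in 12 for Oas1g, 11 for Oas2 and 10 for Clec4a4. These 3 were the only features past limma, and 3145 had an unadjusted p under 0.05, against 1023 expected with no difference. Interferon response genes had a median of 0.48, with 8 members rising adjusted over the list alone and 0 over all genes (camera adjusted p = 7.93e-09; adjusted p = 0.260 with an estimated correlation; fry 0.0143); Irf7 was 1.15 ± 0.21 and Usp18 1.16 higher. Mitosis genes had a median of 0.57, 13 rising adjusted over the list alone (camera adjusted p = 2.58e-09; adjusted p = 0.385 with an estimated correlation), and DNA replication genes of 0.44 (1.26e-07; adjusted p = 0.433 with an estimated correlation). Pan-B cell markers had a median of -0.66, 10 falling adjusted over the list alone (camera adjusted p = 8.66e-09; adjusted p = 0.374 with an estimated correlation; fry 0.0496); Blk was -1.04 and Fcmr -1.06. Follicular (-0.47), marginal zone (-0.22), NF-kB (-0.25), T cell (-0.68), NK (-0.17) and adipose (-0.36) lists had lower medians and neutrophil (0.88) and megakaryocyte (0.57) lists higher ones, 12 lists in all past camera, 0 with an estimated correlation and 3 by fry. Of 21 alternatives the megakaryocyte call was lost in 12, the adipose call in 11, the NK call in 6 and the neutrophil call in 5. With the erythroid score the neutrophil mean went from 0.71 to 0.30 (camera adjusted p = 0.113) and the megakaryocyte mean from 0.51 to 0.21 (0.0852). The pan-B score was -0.50 ± 0.69 in the 5 pristane mice and 0.15 ± 0.07 in the 8 mice with SRBC alone. It was -0.996 and -0.52 in non-diseased Bim-deleted P_1 and P_2 and -1.35 in transgene-only P_2. In diseased P_1 and transgene-only P_1 it was 0.18 each, not lower than the mean with SRBC alone. In the same order the interferon scores were 0.74, 0.69 and 0.89, then -0.07 and -0.08. With SRBC alone the interferon score was -0.17 ± 0.23. Oas1g and Oas2 were still higher in all 5 pristane mice than in every mouse with SRBC alone. The count of features was 1417 without transgene-only mouse P_1, 394 without diseased P_1, 10 without diseased A_1, and 0 when only the mice of these stimuli were fitted. It was 0 or 1 without diseased A_2 or A_3, non-diseased Bim-deleted A_1, A_2, P_1 or P_2, or transgene-only A_1, A_2 or A_3.

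**Figure D3:**
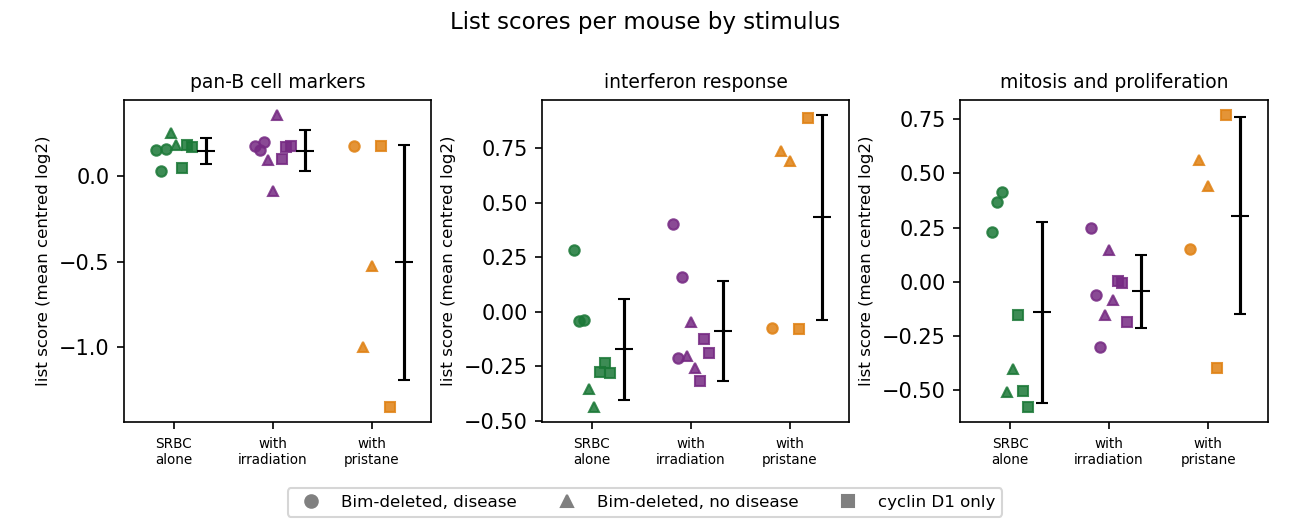
List score (y axis, mean centred log2 intensity) of each mouse by stimulus (x axis) for 3 lists; points are mice, shaped by group, and the bar is the stimulus mean with SD. With pristane the pan-B score of transgene-only mouse P_2 was -1.35 and its interferon score 0.89, and the 5 mice spread widely. Diseased P_1 and transgene-only P_1 had pan-B scores of 0.18 each and interferon scores of -0.07 and -0.08.

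The disease effect under irradiation was set against that under SRBC alone, in 3 against 3 and 3 against 2 mice. By limma 0 features passed, and 962 had an unadjusted p under 0.05, fewer than the 1023 expected with no difference. The smallest p-values belonged to Casp9, an initiator caspase (1.98), Atxn1 (0.69) and Samd4 (-0.49), none significant (adjusted p = 0.544 each). Bcl2l11 was 0.53 ± 0.35 (adjusted p = 0.9798) and Ccnd1 0.31 ± 0.57. The pristane stimulus had 1 diseased mouse and was not set against the others.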

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

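The spacing check was run on 26 list scores and 43 named genes in each of the 3 groups, and no test of an explanation was made here; none was chosen after the values were seen. It asks whether the highest or lowest mouse of a group lies far from its nearest neighbour relative to the range of the group. It marked 34 of 207 sets of values, where chance flags about 1 in 20 groups, or 10.35 sets. The sets are not independent, since many of the named genes are also members of the lists.

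Transgene-only mouse P_2, given pristane, accounts for many of them. It scored 0.77 for mitosis (nearest other transgene-only mouse 0.0018), 0.80 for DNA replication (-0.076) and 0.89 for interferon response (-0.078). It scored -1.35 for pan-B cell markers (0.046), -1.06 for follicular B cells (0.18), -1.0002 for stroma (0.024), -0.73 for adipose (-0.11) and -0.25 for genes named in mantle cell lymphoma (0.039). Among genes it was lowest of its group for Fcrla at 8.53, Ms4a1 at 6.99, Blk at 8.19, Spib at 7.34, Rap1gap at 6.87 and Ntn5 at 6.70. It was highest for Gins2 at 8.32, Ccne2 at 7.59, Tyms at 9.56 and Fcrl5 at 7.71.

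Diseased mouse I_1 was low for the T cell score at -1.003 (nearest -0.34), Cd3d at 8.04 and Lat at 6.77, and high for Spib at 9.39 and the pancreas score at 0.11. Diseased mouse A_2 was low for the pan-B score at 0.028. Non-diseased Bim-deleted mouse A_2 was high for Acoxl at 7.85 (nearest 6.68), 1810046K07Rik at 6.95, Cdk4 at 9.28 and Fcrl5 at 7.72. Of the other non-diseased Bim-deleted mice, P_1 was high for the D-type cyclin score at 0.17, I_2 for the germinal centre score at 0.71, and I_1 low for Tnfrsf19 at 6.46 and Mdm2 at 9.57. Transgene-only mouse I_1 was high for the pancreas score at 0.15, and I_3 for Tnfrsf19 at 6.64. The cause of these values was not tested.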

How the results depend on the processing

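Chosen only after seeing the data were the 60th percentile filter, leaving out the 5 pristane mice, and the erythroid score or Xist level as a covariate. No quantile normalization without background correction, no median scaling and no detection-p filter was run, since the unnormalized columns match no mouse, and no slide block, since no slide is given; the authors' values, planned as an alternative, became the values used. Of the named genes past the threshold, 10 of 25 kept it in every alternative for diseased against non-diseased Bim-deleted mice, 14 of 30 against transgene-only mice and 0 of 3 for pristane, and 0 reversed by limma. Over all named genes, 4137 values kept their side of the threshold, 273 lost and 114 gained it; over the lists 2922, 128 and 137 did, and 6 reversed. The B-1a list kept its call at the preset correlation in all 25 and 26 alternatives (mean 0.60 to 1.03 and 0.59 to 1.05). The replicate block gave 414 genes for diseased against non-diseased Bim-deleted mice (266 shared with the 374), but the numbers do not pair mice: only 1 of 6 matched best with its own number. A signal near background limits Bhlhe41, Sox11, AF067061, Tcstv1, Tnfrsf19, 1810046K07Rik, Acoxl, Clec4a4 and, against transgene-only mice, BC018473 and Hbb-b2. Gained list calls were most frequent for mitosis (10 of 25 for diseased against non-diseased Bim-deleted mice, 9 of 25 for irradiation) and, against transgene-only mice, D-type cyclins and MYC targets (8 of 26 each, diseased). Except where fewer mice or features were fitted, the cause was not tested.

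For diseased against non-diseased Bim-deleted mice (374 genes, 5 lists) the genes were 745 with array weights, 91 fitting only the 2 groups and 806 without the pristane mice (272 shared), and 275 with the Xist level (194 shared). The lists were 1 with an estimated correlation and by fry, 12 with every probe, 2 with the 60th percentile filter, 9 fitting only the 2 groups, 8 with the replicate block, 8 without pristane mice and 3 with the Xist level. Leaving out single mice gave 141 to 692 genes: diseased A_1 141, I_1 163, A_2 164 and P_1 692, and non-diseased P_2 167, A_1 178, I_1 222 and I_3 222. Lists ranged from 1 (diseased A_3 or non-diseased A_2) to 8 (diseased I_2), with 2 or 3 without diseased I_1 or P_1 or non-diseased A_1, I_1 or I_2. The pan-B call was lost in 13 of 25 alternatives (mean -0.014 without pristane mice, adjusted p = 0.985), the T cell call in 11 and that of D-type cyclins in 9. The DNA replication call was lost in 5: with the Xist level (0.013, 0.801), the erythroid score (0.088, 0.249), and without diseased A_3 or non-diseased A_1 or A_2 (adjusted p = 0.0513 to 0.0574). Bcl2l11 ranged from 0.48 to 0.68, past the threshold without diseased P_1 (0.64, adjusted p = 0.0372) or A_3 (0.68, 0.0232).

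For non-diseased Bim-deleted against transgene-only mice (0 genes by limma, 679 at unadjusted p under 0.05, and 0 in every alternative; 5 lists) the lists were 0 with an estimated correlation, by fry and without pristane mice, 2 with no filter and with the erythroid score, 8 with every probe, and 3 with array weights, only the 2 groups, stimulus and the replicate block. Single mice gave 1 to 12: 12 without transgene-only P_2, 1 without A_2, A_3 or P_1 and 3 without I_2, and 1 without Bim-deleted P_1 or P_2 and 2 without I_3. The neutrophil mean reversed to -0.26 without pristane mice and -0.091 with the erythroid score, which also gave DNA replication -0.034 and megakaryocyte -0.31 (adjusted p = 0.0122).

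For diseased against transgene-only mice (1069 genes, 5 lists) the genes were 2618 with array weights and 2690 without pristane mice. Lists were 1 with an estimated correlation and by fry, 8 with no filter, 11 with every probe and 9 without pristane mice. Single mice gave 576 to 1960 genes: diseased A_2 576, A_1 615 and I_1 696, transgene-only I_3 684, A_2 707 and P_2 1960; lists 5 to 10 (P_2). The mitosis mean reversed to -0.025 with the erythroid score and was 0.15 with the Xist level (adjusted p = 0.123). The erythroid score also ended the calls of DNA replication (0.054, 0.499) and T cells (-0.17, 0.266).

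For irradiation (0 genes by limma, 958 at unadjusted p under 0.05; 3 lists) mice without disease gave 1 gene and 7 lists, only the 2 stimuli 5 lists, array weights 5, the erythroid score 8, and an estimated correlation and fry 0. Single mice gave 0 to 0 genes and 2 to 8 lists (diseased I_1 8, A_1 and I_3 6, A_3 5). DNA replication reversed to -0.13 with the erythroid score (adjusted p = 1.91e-04). The erythroid call was lost in 9 of 24 alternatives, p53 in mice without disease (0.049) and T cells with the erythroid score (-0.21). For pristane (3 genes, 12 lists) the genes were 0 with no filter or only the 2 stimuli, 9 with trend and robust, 80 with array weights, 35 with the 60th percentile filter, 253 with the erythroid score and 207 in mice without disease; lists were 0 with an estimated correlation and 3 by fry. The megakaryocyte call was lost in 12 of 21 alternatives, adipose in 11, NK in 6 and neutrophil in 5. Single mice gave 0 to 1417 genes: transgene-only P_1 1417, diseased P_1 394 and A_1 10, and 0 or 1 without diseased A_2 or A_3, Bim-deleted non-diseased A_1, A_2, P_1 or P_2, or transgene-only A_1, A_2 or A_3; lists 8 to 15. The interaction gave 0 to 2 genes (2 without non-diseased A_1, 1 without non-diseased A_2 or diseased A_3).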

Other observations

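The tests chosen only after the result was seen were both tests of the B-1a list, the strain variant test, the Acoxl and Bcl2l11 correlation and both counts of neighbouring genes; the test of antigen-presenting cells and the counts of other splits were written before.

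By a definition set after H2-Aa had been seen, 7 named genes stood at separate levels across mice, with a gap over 1.5 (log2) and over 0.4 of the range, and at least 3 mice on each side. Fcer1g, the Fc receptor gamma chain, was low in 4 mice (1 diseased, 0 non-diseased Bim-deleted and 3 transgene-only). Hbb-b2 was low in 5 transgene-only mice, BC018473 in 12 mice including all 8 transgene-only ones, Necap2 in 4, Zfp330 in 3, Psmb9 in 8 and Casp9 in 3, all diseased. Among the genes called between diseased and non-diseased Bim-deleted mice, 16 pairs of called genes were neighbours and 14 of these moved the same way. Of these pairs 5 lie in the cluster of near-identical genes that holds Tcstv1 and AF067061 and 2 in that of C130026I21Rik, Sp110 and Sp140, which may share probe signal, so the pairs are not independent. Random sets had a median of 6 pairs and at most 17, and 2 of 1000 draws had as many as 16. With the genes of these clusters set aside 9 pairs were left, and 166 of 1000 draws had as many (median 6), so an excess beyond the clusters is not shown.

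The B-1a list was higher in diseased than in non-diseased Bim-deleted mice, and a larger share of B cells could raise it. The B-1a score minus the pan-B score was 0.63 higher in diseased mice (0.45 ± 0.25 against -0.17 ± 0.54 SD, n = 7 each, exact permutation p = 0.0175). Of 7 diseased mice 1 lay above all non-diseased ones. A larger share alone gives no rise only if the B-1a list follows the pan-B list. Transgene-only P_2 had a pan-B score of -1.35 but the highest B-1a score of its group, -0.08. Non-diseased Bim-deleted P_1 had -0.996 and -0.24, so the subtraction alone cannot decide. The subtraction replaced a comparison of 95% confidence intervals over all mice, which overlapped (B-1a 0.88, 0.63 to 1.13, and pan-B 0.25, -0.20 to 0.70). Without pristane mice the pan-B difference was -0.01 (-0.22 to 0.19) and the B-1a difference 0.89 (0.55 to 1.23). Among those mice the B-1a list thus differed without a pan-B difference. The unequal stimuli of the groups are argued against as the whole cause by the B-1a difference with stimulus as a term, 0.88 (95% interval 0.66 to 1.09), where the pan-B difference went from 0.25 to 0.16. Whether disease brings more B-1a-like cells, a higher level of these genes per cell, or other cells that carry them was not tested.

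H2-Aa and Psmb9, both in the MHC and chosen after their values were seen, were low in the same 8 mice (3 of 7 diseased, 5 of 7 non-diseased Bim-deleted and 0 of 8 transgene-only) and high in both in 14; MHC genes may share probe signal with near-identical copies. H2-Aa stood at 6.63 to 6.97 in the low mice and 8.61 to 11.08 in the others, and Psmb9 at 7.06 to 7.91 and 9.50 to 10.70. H2-Ob, also in the MHC, was low in 10 mice, among them all 8 of these (7.07 to 8.10) and non-diseased Bim-deleted P_1 (8.401) and transgene-only P_2 (7.85), with the others at 9.66 to 10.28. For fewer antigen-presenting cells, the test written before took the widest range of Cd74, H2-Ab1 and H2-Eb1 over the 22 mice, 2.35 against 4.45 for H2-Aa. It cannot decide, because the lowest value of each came from transgene-only P_2, not from the 8 low mice. Looked at afterwards, the 8 low mice had Cd74 at 13.28 to 14.19, H2-Ab1 at 11.62 to 13.07 and H2-Eb1 at 12.48 to 13.35. The others had 12.19 to 14.07, 10.72 to 13.03 and 11.08 to 13.40, which argues against fewer such cells in the low mice. A strain variant of a genome segment remains open: 0 pairs of such genes were adjacent, but random draws had at most 1, so the test could not decide, and H2-Aa and H2-Ob (gap 1.26) missed its definition.

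Acoxl, the neighbour of Bcl2l11 with 0 tested genes between, rose in diseased mice, and Bcl2l11 was 0.56 higher without passing the threshold. A shared change of the locus may link them: over the 7 diseased mice Pearson's r was 0.85 (exact permutation p = 0.00516) and Spearman's rho 0.93 (exact permutation p = 0.00675), and r was 0.77 without mice A_3 and I_2, farthest from the median of Acoxl. Against this, transgene-only mice had Bcl2l11 at 8.23 with Acoxl at background (6.51), and non-diseased Bim-deleted A_2 had Acoxl at 7.85 with Bcl2l11 at 7.69, so a link outside diseased mice is not shown. This was 1 relation, with too few mice in each stimulus to test it within, and an effect of the deletion on transcription across the locus was not tested.

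Other splits of the mice were counted for each comparison, 100 each. Diseased against non-diseased Bim-deleted mice gave 374 genes and no other split more than 9, so that only the real split, 1 of 100, gave as many. This is the smallest share that 100 splits can give. For diseased against transgene-only mice also only the real split, 1 of 100, gave as many as 1069, with the highest other at 160. For non-diseased Bim-deleted against transgene-only mice the real count was 0 by limma (highest other 1; 679 at unadjusted p under 0.05), and for irradiation also 0 (highest other 7; 958). A count of 0 is matched by all 100 of 100 splits by construction, so these splits do not test chance. For pristane 4 of 100 splits gave at least the real 3, so a chance split seldom gives as many, yet the highest other gave 2048, far above the real count, which points to a structure of the samples whose cause was not tested. That split set transgene-only P_1 and 4 mice with SRBC alone against the other 4 pristane mice and 4 mice with SRBC alone. The side of transgene-only P_1 held the lowest erythroid scores of the mice compared, -3.10 to -0.57 against -0.03 to 1.35. The split also kept the other 4 pristane mice together, so its count may hold part of the pristane difference.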
